A study of Rattus norvegicus with 18 samples.

How the data were processed

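RNA sequencing of liver from male rats was used, in 6 groups of 3 libraries. Per the labels, the normal control and the obese control were given water, 1 obese group was given orlistat as the positive control, and 3 obese groups were fed plantain at a low, medium or high dose. The labels give an age of 18 weeks and no dose amounts. They do not say that the 3 libraries of a group come from separate animals, so each p-value measures only the spread between these libraries, which may be technical in part.

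Per the labels' protocols, frozen liver was used, with 1 µg of RNA per sample and an Illumina library kit, sequenced on an Illumina NovaSeq instrument. The submitters' processing notes list CASAVA 1.7, Bowtie 0.12.2 and the build mm8. That build is of the mouse, while the 32883 identified genes carry rat Ensembl identifiers; the rat build and annotation release are not given in the sources used here. Coordinates are printed as the file gives them, with the build not named.

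The authors deposited 1 table of FPKM (fragments scaled by gene length and by the sequenced total) for 33657 genes, with 1 value per gene and library. Per the file headers, each gene also has a length, coordinates, a type and a symbol. In each library the deposited FPKM times the gene length was a whole multiple of 1 step for 100% of the genes (tolerance 0.001), so the whole reads or fragments behind the values were recovered. They came to between 16.6 and 26.2 M (mega) per library. The total used by the authors for scaling was 0.9661 to 1.0468 times the recovered total, so the deposited FPKM carry a further scale factor per library whose source is not given in the sources used here. The factor differed between groups (0.974 ± 0.005 in the obese control, 1.036 ± 0.012 with orlistat and 1.028 ± 0.003 at the high dose; mean ± SD, n = 3), so it is confounded with group. The sums of FPKM per library ran from 531108 to 609662. The reference gene table matched 0 of the identifiers, so symbols come from the file; 774 genes had no symbol, and placeholder and clone names were treated as no symbol, a choice made after the data were seen. Reads of near-identical gene copies cannot be told apart from the table, and the strand setting of the counting is not given in the sources used here.

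Values were taken as log2(FPKM + 1) for genes with at least 1 FPKM in at least 3 samples, which left 11945 genes, 10655 of them protein coding. Groups were compared with limma 3.58.1 (R 4.3.3) in 1 fit of all 6 groups with a mean-variance trend and no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All limma tests were two-sided. The comparisons were obese control against normal control, each of the 4 treatments against the obese control, high dose against orlistat, a trend with equal steps over the obese control and the 3 doses, and an F-test of equality of the 3 doses. With 3 against 3 libraries an exact permutation test of a single gene cannot give a p below 0.1.

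A set of 30 gene lists for liver pathways and cell types was fixed before the data were examined; 26 had at least 5 tested members and were tested with camera (limma, preset correlation 0.01), adjusted over the lists within a comparison. The lists were fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, fatty acid oxidation and PPARalpha targets, lipoproteins and lipid droplets, bile acid synthesis and transport, glucose production and insulin response, amino acid breakdown and urea cycle, cytochrome P450 drug metabolism, NRF2 antioxidant and conjugation genes, inflammation, acute phase proteins, interferon response, fibrosis and stellate cells, the unfolded protein and amino acid stress response, heat shock, the circadian clock, the cell cycle, growth hormone and male-type liver genes, oxidative phosphorylation, immediate early genes, mitochondrially encoded transcripts, and markers of Kupffer cells and macrophages, lymphocytes, neutrophils, bile duct cells, liver endothelial cells, fat cells, red blood cells, exocrine pancreas and hepatocytes. The growth hormone and male-type list also holds female-type genes, such as Cux2 and Srd5a1. A rise or fall of that list therefore gives no direction of growth hormone action or of male-type expression. The immediate early genes and the mitochondrially encoded transcripts were classed as RNA quality lists, not as pathways. Each list was also tested with an estimated correlation and with the rotation test fry, which asks whether the genes of a list move on balance and does not compare them with other genes. Named genes followed a rule set at the same time: the 5 largest rises and 5 largest falls per comparison among genes past the threshold whose groups did not overlap, up to 4 members of each list by smallest p, the 5 smallest p-values in each direction for the trend, and 10 for the F-test.

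Comparisons that share the obese control libraries were set beside 20 simulated draws of unchanged groups with the same spread. The alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, rescaling to TPM, quantile normalization, a fit of only the compared groups, robust moderation, the replicate number as a block, and leaving out each library in turn. Weights from limma's voom on the recovered reads, the trend without the obese control, comparisons of the treatments with the normal control and of the high with the low dose, and counts of treated libraries against both controls were added after results were seen.

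The fit was tested on simulated counts for the real genes with a median dispersion of 0.00235, in which 200 genes were changed by log2 0.5 or 1. In the real comparisons 1806 to 6578 genes passed, so the shares recovered need not be the same there. The simulated libraries were independent draws, so the false calls do not cover shared RNA or other differences between whole groups. For obese control against normal control, with 11715 simulated genes tested, 82 of 99 genes changed by log2 1 and 63 of 100 changed by log2 0.5 were recovered, and 7 of 11516 unchanged genes were called. Among genes of at least 10 FPKM, 37 of 40 changed by log2 1 were recovered. For high dose against obese control the figures were 86 of 99, 59 of 98 and 13 of 11509, with 28 of 28 at log2 1 and at least 10 FPKM. A pass mark of 90% recovery, first set over all genes changed by log2 1, was not reached, and after this was seen it was set for genes of at least 10 FPKM instead. For obese control against normal control the median estimate of a change of log2 1 was 0.85 over all such genes and 0.95 among those of at least 10 FPKM. In a simulated shift of 1 list, camera called that list and 0 of 25 unchanged lists in each of the 6 comparisons of groups, and fry called 1 unchanged list in the low-dose comparison.

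Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. Body weights, histology, protein levels and raw reads were not analysed here. The values of some single members of the gene lists are not reported here; they remain in the counts of the lists.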

Results

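Liver RNA of male rats aged 18 weeks was sequenced in 18 libraries, 3 for each of 6 groups: normal control, obese control, orlistat, and plantain at a low, medium or high dose. Orlistat, a lipase inhibitor used against obesity, was the positive control per the labels, and plantain was the treatment under study. The recovered reads per library (M for mega) ran from 25.5 to 26.2 M in the normal control, 19.2 to 24.3 M in the obese control and 17.4 to 20.3 M with orlistat. They ran from 19.6 to 23.9 M at the low dose, 19.1 to 21.9 M at the medium dose and 16.6 to 20.6 M at the high dose. Albumin took 10.83% ± 0.39 of the reads with orlistat and 12.23% ± 0.26 in the obese control (mean ± SD, n = 3). Values are log2 differences of FPKM + 1 with the standard error of the limma fit, and adjusted p-values are limma's. Replicates lay close together, with a median standard error of 0.069 in comparisons of 2 groups.

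The comparison of obese and normal controls asked what differed in the liver of the obese rats without treatment. Cholesterol synthesis genes were lower in the obese control, and macrophage markers were higher. Akr1c2, an aldo-keto reductase gene (ENSRNOG00000029844, chromosome 17, 69388335 to 69404341), rose from 4.98 ± 0.50 to 103 ± 2.4 FPKM (mean ± SD, n = 3), a log2 change of 4.12 ± 0.07 with an adjusted p of 2.34e-16. Reads of Akr1c2 could be split with its close relatives, so its level is uncertain. Cldn1, a tight junction gene, rose by 3.39 ± 0.07, and Crot, which encodes a peroxisomal carnitine octanoyltransferase, rose by 2.82 ± 0.03. Nrg4, which encodes a secreted growth factor, fell from 20.3 ± 1.45 to 1.01 ± 0.21 FPKM, and Pnpla3, a lipid droplet gene, fell from 11.7 ± 0.90 to 0.43 ± 0.14 FPKM. The other genes with large changes were the phosphate transporter Slc34a2 (3.00 ± 0.05) and Tor3a (2.68 ± 0.10) among those that rose, and Inmt (-3.18 ± 0.10), the potassium channel gene Kcnj15 (-3.12 ± 0.12) and the uridine phosphorylase gene Upp2 (-2.89 ± 0.06) among those that fell.

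Of 25 genes of cholesterol synthesis and uptake, 24 fell and 0 rose (median -0.95, camera adjusted p = 6.2e-18). Among them were Fdps (-1.64 ± 0.04), Fdft1 (-1.63 ± 0.03) and Cyp51 (-1.58 ± 0.03). Of 20 genes of fatty acid and triglyceride synthesis, 13 fell and 6 rose (median -1.36, camera adjusted p = 0.00043; adjusted p = 0.051 with an estimated correlation). Acly (-2.59 ± 0.03), Acaca (-2.55 ± 0.04), Thrsp (-1.73 ± 0.01) and the desaturase Scd (-1.34 ± 0.02) fell. In fatty acid oxidation 17 of 26 genes rose and 9 fell (camera adjusted p = 0.054): Cyp4a2 (1.42 ± 0.03) and Cyp4a1 (0.63 ± 0.02) rose while Ehhadh (-0.86 ± 0.02) and Cpt1a, the entry step of mitochondrial oxidation (-0.75 ± 0.02), fell. Lipoprotein and lipid droplet genes had 18 members that rose and 8 that fell of 29 (camera adjusted p = 0.0037), led by Apoa1 (1.10 ± 0.02); quantile normalization ended that call (adjusted p = 0.11). In bile acid synthesis and transport 13 of 18 genes fell and 3 rose (median -0.21, camera adjusted p = 0.0086); Akr1d1 (-0.80 ± 0.02) and Cyp27a1 (-0.51 ± 0.02) fell, while Cyp8b1 (1.09 ± 0.02) and the phospholipid exporter Abcb4 (1.39 ± 0.03) rose.

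Genes of glucose production and insulin response fell in 14 of 18 cases (median -0.29, camera adjusted p = 0.00013), with the glucose transporter Slc2a2 at -1.37 ± 0.02 and glycogen synthase Gys2 at -1.41 ± 0.04. Amino acid breakdown and urea cycle genes fell in 16 of 20 cases (median -0.26, camera adjusted p = 0.00011), including Sds (-1.44 ± 0.02), Gpt (-1.21 ± 0.04) and Ass1 (-0.83 ± 0.02). The circadian clock list fell in 12 of 17 cases (median -0.90, camera adjusted p = 0.00050): Per3 (-2.16 ± 0.05) and Dbp (-1.59 ± 0.03) fell and Arntl, which encodes the activator BMAL1, rose (2.44 ± 0.08). Heat shock genes rose in 11 of 17 cases (median 0.42, camera adjusted p = 0.0026). Fkbp4 was at 1.10 ± 0.02 and Hsph1 at 1.08 ± 0.04. The unfolded protein and amino acid stress list had 12 members that rose and 4 that fell of 21 (camera adjusted p = 0.017; adjusted p = 0.051 with an estimated correlation); the chaperone gene Hspa5 rose (0.80 ± 0.02) and Xbp1 fell (-1.18 ± 0.03). Acute phase genes rose in 12 of 17 cases (median 0.27, camera adjusted p = 0.00050; adjusted p = 0.052 with an estimated correlation and 0.065 under quantile normalization), with Hpx at 0.81 ± 0.01 and Fga at 0.51 ± 0.01, while the iron hormone gene Hamp fell (-0.62 ± 0.03). Members of the growth hormone and male-type liver list rose in 10 of 18 cases (camera adjusted p = 0.012, and 0.067 with an estimated correlation). That list mixes male-type and female-type genes, so its direction here and below is not that of growth hormone action.

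Markers of Kupffer cells and macrophages rose in 13 of 13 cases (median 0.74, camera adjusted p = 2.8e-08). Cd5l was at 0.82 ± 0.04, C1qa at 0.80 ± 0.04 and Cd163 at 0.75 ± 0.04. Fibrosis and stellate cell genes rose in 11 of 19 cases and fell in 1 (median 0.37, camera adjusted p = 0.00050). The matrix gene Sparc was at 0.80 ± 0.03 and Fn1, which encodes fibronectin, at 0.63 ± 0.03. Endothelial markers rose in 7 of 11 cases (median 0.24, camera adjusted p = 0.012), with Clec4g at 0.78 ± 0.06. Red blood cell genes rose in 5 of 8 cases (median 0.75, camera adjusted p = 0.017; adjusted p = 0.051 with an estimated correlation). Alas2 was at 0.79 ± 0.10. Hba-a2 was at 0.97 ± 0.12, and its reads could be split with the other alpha globin genes. Mitochondrially encoded transcripts rose in 11 of 13 cases (median 0.35, camera adjusted p = 0.0036; adjusted p = 0.36 with an estimated correlation and 0.32 under quantile normalization, where ATP6 turned direction). Hepatocyte markers had 9 members that rose and 3 that fell of 14 (camera adjusted p = 0.017; adjusted p = 0.21 with an estimated correlation), and quantile normalization reversed the direction of that list. Counts adjusted over the list alone equalled those given, except 13 that rose for acute phase genes, 7 that rose for red blood cells and 4 that fell for hepatocytes.

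The remaining lists did not pass in this comparison. Cytochrome P450 genes had 11 members that fell and 6 that rose of 20 (median -0.18, camera adjusted p = 0.056). NRF2 antioxidant and conjugation genes had 7 and 4 of 18 that rose and fell (camera adjusted p = 0.38), inflammation 6 and 3 of 15 (0.26), interferon response 8 and 5 of 21 (0.22), cell cycle 2 and 1 of 7 (0.38), oxidative phosphorylation 9 and 9 of 27 (0.70), immediate early genes 7 and 5 of 15 (0.78) and lymphocytes 4 and 0 of 8 (0.17). The lists with fewer than 5 tested members were not tested as lists. Of these, neutrophil markers had 2 of 3 that rose, fat cell markers 3 of 4, exocrine pancreas 1 of 2, and bile duct markers 1 of 3 that fell. Adjusted over the list alone, 3 of 3 neutrophil markers rose, and the other counts in this group were unchanged. Single genes in these lists changed strongly, among them Por (-1.57 ± 0.03), the electron donor of the cytochromes P450, Aldh1a1 (1.42 ± 0.02), Gclm (-1.19 ± 0.02), the neutrophil chemokine Cxcl1 (1.28 ± 0.10), the cell cycle inhibitor Cdkn1a (2.12 ± 0.09) and Gadd45g (1.68 ± 0.05).

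In all, 6578 of 11945 genes passed in obese against normal controls, 3191 higher and 3387 lower, and 158 of the rises and 209 of the falls exceeded log2 1. The values of the groups did not overlap for 62.5% of genes, against 10% by chance. Rescaling to TPM moved the median of all genes by -0.11 and gave 1973 higher and 4570 lower, so changes are stated relative to the median gene of the deposited scale. TPM moved that median by 0.14 for orlistat and 0.15 for the high dose against the obese control.

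**Figure D1:**
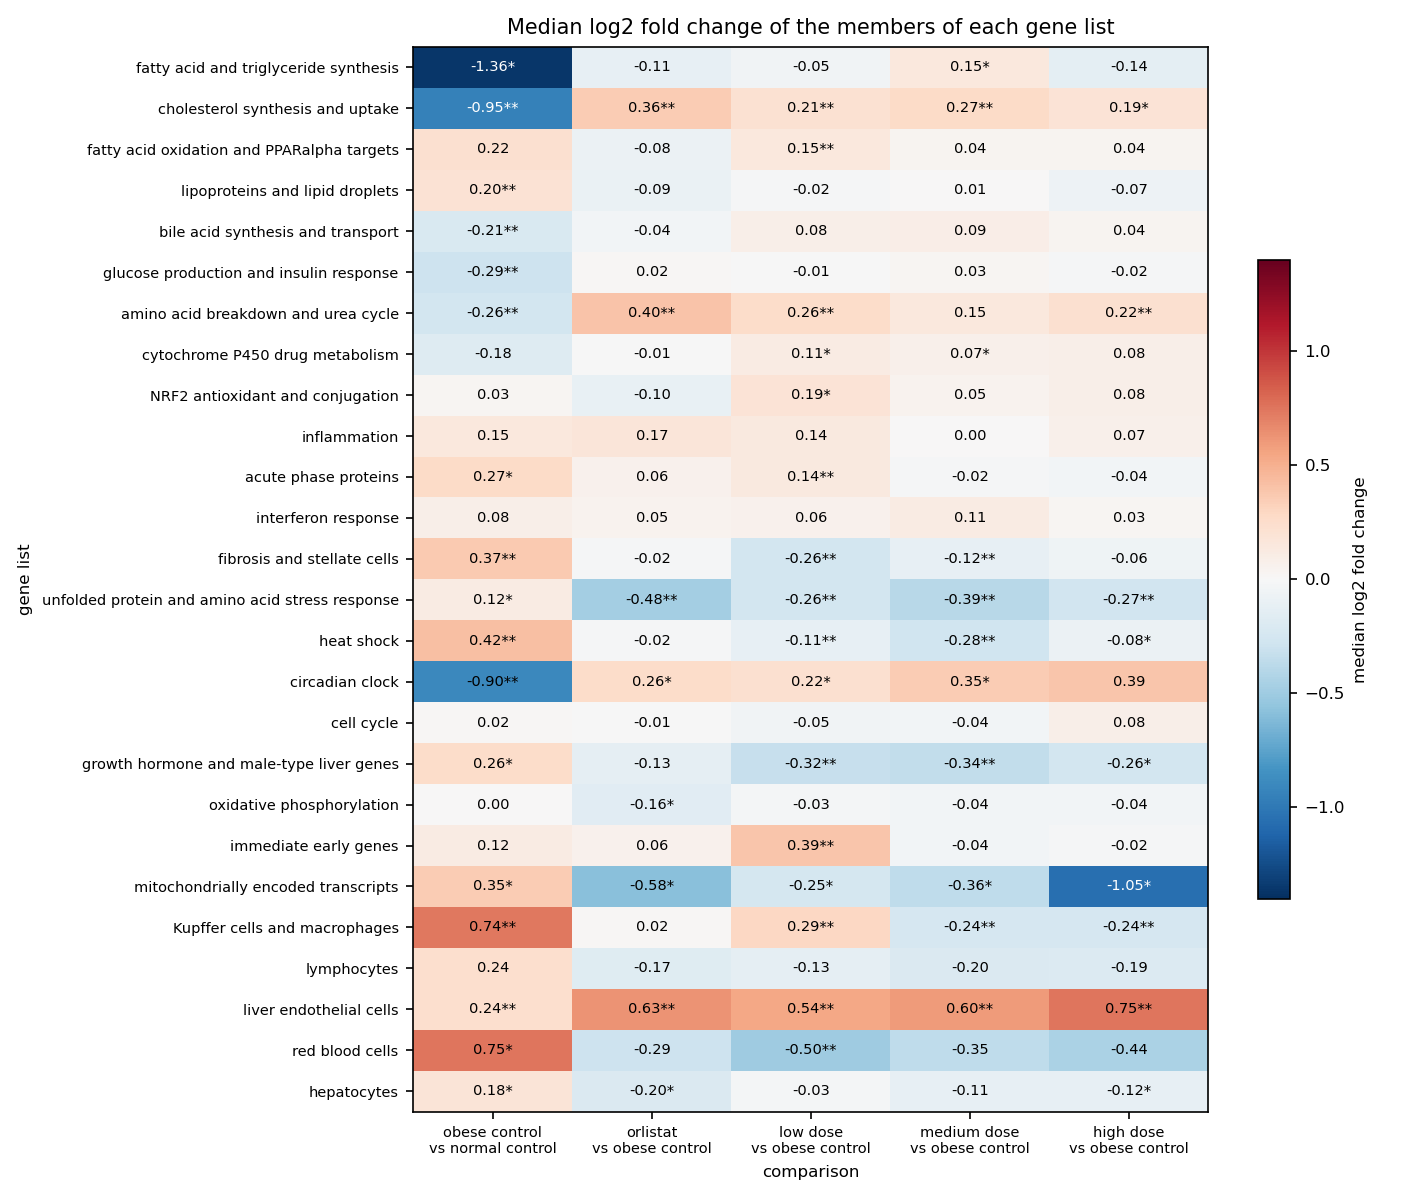
Median log2 fold change of the members of the 26 tested gene lists (vertical axis) in 5 comparisons (horizontal axis), n = 3 libraries per group. Colour and printed value give the median; 1 star marks camera's adjusted p under 0.05 with the preset correlation, and 2 stars mark lists that also passed with an estimated correlation. The hepatocyte list turned direction under quantile normalization in the obese, orlistat and high-dose columns. The endothelial list was 0.63, 0.54, 0.60 and 0.75 higher in the 4 treatments than in the obese control.

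The orlistat group was set against the obese control as the positive control of the study. Cyp7a1, the rate-limiting enzyme of bile acid synthesis (ENSRNOG00000009488, chromosome 5, 19358734 to 19368431), rose from 19.0 ± 0.12 to 66.3 ± 0.27 FPKM (mean ± SD, n = 3), a log2 change of 1.75 ± 0.03 with an adjusted p of 3.14e-15, and in the normal control it stood at 33.6 ± 0.56 FPKM. Nrg4 rose by 2.19 ± 0.11 and the acetyltransferase gene Nat8f3 by 1.92 ± 0.11. The carboxylesterase gene Ces2e rose from 0.40 ± 0.07 to 6.22 ± 0.36 FPKM, with reads that could be split with its relatives. Akr1c2 (-3.12), Tff3 (-2.41), Slc34a2 (-1.91) and Creld2, a gene of the endoplasmic reticulum stress response (-1.85), fell. LOC103690108, a class I histocompatibility gene, was listed at 0 in each obese control library and at 5.51 ± 0.69 FPKM with orlistat. It was at 0.0595 ± 0.075 FPKM in the normal control and 0.039 ± 0.039 at the low dose. Of 33657 genes it was the only 1 found at 2 FPKM or more, or under 0.2, in every library, with libraries of both kinds. It was on in 9 libraries (lowest 4.86 FPKM) and off in 9 (highest 0.144), alike within each of the 6 groups. The cause was not tested. Rps6 was lower (-3.45 ± 0.83) but varied widely between replicates, with 59.1 ± 12.6 FPKM in the obese control and 30.2 ± 24.4 in the normal control, and it has many near-identical copies, so its value is uncertain.

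Amino acid breakdown and urea cycle genes rose with orlistat in 16 of 20 cases and fell in 2 (median 0.40, camera adjusted p = 5.8e-08): Gpt rose by 1.51 ± 0.04, Sds by 1.35 ± 0.02 and the urea cycle entry enzyme Cps1 by 0.56 ± 0.02. Cholesterol genes rose in 19 of 25 cases and fell in 3, or 20 and 4 adjusted over the list alone (median 0.36, camera adjusted p = 2.2e-06). Tm7sf2 was at 0.93 ± 0.04 and Insig1 at 0.67 ± 0.04. The unfolded protein and amino acid stress list fell in 17 of 21 cases (median -0.48, camera adjusted p = 7.9e-08). Hyou1 was at -1.41 ± 0.04, Hspa5 at -0.82 ± 0.02 and Pdia4 at -0.67 ± 0.02. Endothelial markers rose in 9 of 11 cases and fell in 1 (median 0.63, camera adjusted p = 3.3e-06). Kdr, the main VEGF receptor, was at 0.91 ± 0.04, Lyve1 at 0.91 ± 0.04 and the scavenger receptor gene Stab2 at 0.88 ± 0.04. The circadian clock list rose in 10 of 17 cases and fell in 4 (camera adjusted p = 0.044; adjusted p = 0.17 with an estimated correlation and 0.068 under quantile normalization). Per3 was at 1.11 ± 0.05 and Dbp at 0.74 ± 0.03.

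Mitochondrially encoded transcripts fell in 13 of 13 cases with orlistat (median -0.58, camera adjusted p = 5.3e-06; adjusted p = 0.29 with an estimated correlation). ND5 was at -0.64 ± 0.05. The share of reads on mitochondrial transcripts was 5.73% ± 0.24 with orlistat against 8.11% ± 0.26 in the obese control and 6.45% ± 0.23 in the normal control (mean ± SD, n = 3). Nuclear genes of oxidative phosphorylation fell in 17 of 27 cases and rose in 4 (median -0.16, camera adjusted p = 0.0069; adjusted p = 0.29 with an estimated correlation and 0.41 under quantile normalization). Cox4i1 was at -0.40 ± 0.02. Hepatocyte markers fell in 11 of 14 cases (median -0.20, camera adjusted p = 0.0013; adjusted p = 0.20 with an estimated correlation), and quantile normalization turned the direction of that list. Fat synthesis genes went both ways, with 9 that rose and 10 that fell of 20 (median -0.11, camera adjusted p = 0.56): Scd fell (-1.53 ± 0.02) and Thrsp rose (0.54 ± 0.01). In the list of growth hormone genes (6 rose and 9 fell of 18, camera adjusted p = 0.19), Socs2 and Cish, which are induced by growth hormone, fell (-1.71 and -1.65). Bile acid genes had 8 that rose and 8 that fell of 18 (camera adjusted p = 0.59), with a median of -0.04 and a mean of 0.23. Kupffer cell markers had 4 that rose and 1 that fell of 13 (camera adjusted p = 0.53). In total 6188 genes passed with orlistat, 3133 higher and 3055 lower (4989 and 1562 as TPM), and the groups did not overlap for 58.2% of genes, against 10% by chance.

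**Figure D2:**
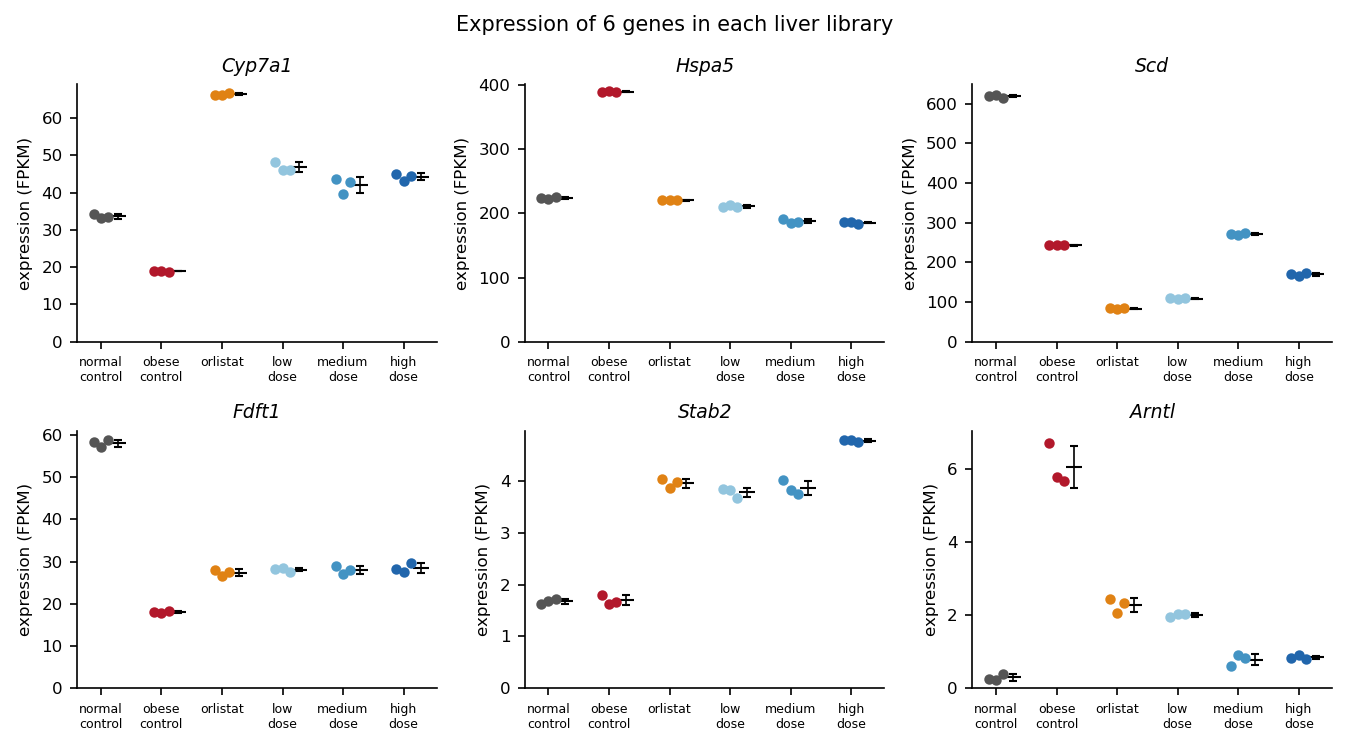
Expression in FPKM (vertical axes, from 0) of Cyp7a1, Hspa5, Scd, Fdft1, Stab2 and Arntl in each of the 18 libraries, by group (horizontal axes). Points are libraries and the black mark with bars is the mean ± SD of 3 libraries; Cyp7a1 was at 19.0 in the obese control and 66.3 with orlistat, and Hspa5 at 390 in the obese control against 186 to 224 in the other 5 groups.

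Low-dose plantain was compared with the obese control to ask what the smallest dose changed. Cyp7a1 rose by 1.26 ± 0.03 (adjusted p = 2.7e-13, n = 3 per group), Upp2 by 1.29 ± 0.06 and Nrg4 by 1.48 ± 0.11. Ces2e rose from 0.40 ± 0.07 to 6.66 ± 0.74 FPKM. Akr1c2 (-2.27), the collagen cross-linking enzyme gene Lox (-1.84) and Creld2 (-1.47) fell. LOC100912538, listed as centrin-3-like, rose by 1.77 ± 0.32. The short microRNA gene Mir3557 fell (-1.43), a call that a pseudocount of 0.1 ended (adjusted p = 0.068). Tspan4 (2.72 ± 0.84) and LOC108348080 (-2.34 ± 0.74) passed with wide spread between replicates. The call on Tspan4 ended without obese control replicate 2 (2.24) or 3 (2.43) or low-dose replicate 3 (2.39). That on LOC108348080 ended without obese control replicate 1 (-2.04), low-dose replicate 1 (-2.27) or 3 (-2.35), and with voom on the recovered reads (adjusted p = 0.07).

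Endothelial markers rose at the low dose in 9 of 11 cases (median 0.54, camera adjusted p = 9.5e-08). Stab2 was at 0.82 ± 0.04, Lyve1 at 0.69 ± 0.04 and Fcgr2b at 0.65 ± 0.05. Kupffer cell markers rose in 12 of 13 cases (median 0.29, camera adjusted p = 1.8e-05). Clec4f was at 0.44 ± 0.04 and C1qa at 0.39 ± 0.04. Acute phase genes rose in 13 of 17 cases (median 0.14, camera adjusted p = 3.5e-06). Hamp was at 0.70 ± 0.03 and Hp at 0.38 ± 0.01. Immediate early genes, classed as an RNA quality list, rose in 10 of 15 cases and fell in 3 (median 0.39, camera adjusted p = 0.00093). Egr1 was at 1.14 ± 0.03 and Jun at 0.80 ± 0.03. Cholesterol genes rose in 17 of 25 cases and fell in 0 (median 0.21, camera adjusted p = 5.7e-06). Fdft1 was at 0.61 ± 0.03. Fatty acid oxidation genes rose in 15 of 26 cases and fell in 4, or 16 and 4 adjusted over the list alone (median 0.15, camera adjusted p = 0.00079). Ehhadh was at 0.75 ± 0.02 and Cpt1a at 0.60 ± 0.02. Amino acid breakdown genes rose in 13 of 20 cases and fell in 2, or 14 and 4 adjusted over the list alone (median 0.26, camera adjusted p = 6.0e-06). Ass1 was at 0.41 ± 0.02.

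Fibrosis and stellate cell genes fell at the low dose in 11 of 19 cases and rose in 0 (median -0.26, camera adjusted p = 2.0e-05). Col3a1 was at -0.34 ± 0.03 and Lrat at -0.50 ± 0.05 beside Lox. The unfolded protein and amino acid stress list fell in 13 of 21 cases and rose in 7 (median -0.26, camera adjusted p = 0.00043). Hyou1 was at -1.17 ± 0.04 and Hspa5 at -0.88 ± 0.02. Heat shock genes fell in 9 of 17 cases (camera adjusted p = 0.0024), growth hormone genes in 10 of 18 (median -0.32, camera adjusted p = 0.00061) with Bcl6 at -0.93 ± 0.05, and red blood cell genes in 5 of 8 (median -0.50, camera adjusted p = 0.012) with Alas2 at -0.74 ± 0.10. The calls on these 5 lists and the 7 of the paragraph above held with an estimated correlation. The call was lost for the cytochrome P450 list (12 rose and 3 fell of 20, camera adjusted p = 0.0083; adjusted p = 0.083 with an estimated correlation), the NRF2 list (7 and 3 of 18, 0.023; adjusted p = 0.22 with an estimated correlation), the clock (9 and 4 of 17, 0.020; adjusted p = 0.06 with an estimated correlation) and the mitochondrial transcripts (0 and 8 of 13, 0.00056; adjusted p = 0.26 with an estimated correlation). Adjusted over the list alone, 13 of 13 mitochondrial transcripts fell, 9 NRF2, 10 clock and 3 heat shock genes rose; ATP6 turned direction under quantile normalization. In total 3947 genes passed, 2183 higher and 1764 lower (2672 and 1302 as TPM), and the groups did not overlap for 44.8% of genes, against 10% by chance.

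Medium-dose plantain was compared with the obese control in the same way. Cdh17, a cadherin gene, rose by 2.44 ± 0.05 (adjusted p = 1.94e-14, n = 3 per group), the receptor gene Ddr1 by 2.49 ± 0.08, Nat8f3 by 1.55 ± 0.11 and Cyp7a1 by 1.10 ± 0.03. Ces2e rose to 11.3 ± 0.57 FPKM. LOC103690108 stood at 11.2 ± 0.83 FPKM where the obese control was listed at 0, in the on or off pattern by group given above, with the low dose at 0.039. Akr1c2 (-3.46), Abhd3 (-2.13) and Arntl (-1.98) fell. The first of 2 gene records named Nfs1 was lower (-3.19 ± 0.58), but it varied from library to library, with 6.23 ± 8.78 FPKM in the normal control, and reads could be split between the records. LOC679739 was lower as well (-2.33 ± 0.71), a call that ended without obese control replicate 3 (-2.02) and with voom on the recovered reads (adjusted p = 0.062).

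The unfolded protein and amino acid stress list fell at the medium dose in 17 of 21 cases (median -0.39, camera adjusted p = 1.4e-09). Hyou1 was at -1.44 ± 0.04, Manf at -1.09 ± 0.04 and Hspa5 at -1.05 ± 0.02. Endothelial markers rose in 9 of 11 cases (median 0.60, camera adjusted p = 1.9e-06). Stab2 was at 0.85 ± 0.04 and Kdr at 0.76 ± 0.04. Kupffer cell markers fell in 11 of 13 cases and rose in 0 (median -0.24, camera adjusted p = 5.3e-05). Marco was at -0.86 ± 0.09, Cd5l at -0.82 ± 0.04 and Cd163 at -0.72 ± 0.04. Cholesterol genes rose in 18 of 25 cases and fell in 1, or 21 and 3 adjusted over the list alone (median 0.27, camera adjusted p = 5.0e-06), with Stard4 at 0.77 ± 0.04, while Insig1, which holds back the pathway, fell (-1.09). Members of the mixed growth hormone list fell in 11 of 18 cases, or 12 adjusted over the list alone (median -0.34, camera adjusted p = 8.9e-05). Socs2 was at -1.71 ± 0.07, Cux2 at -1.32 ± 0.08 and Srd5a1 at -0.97 ± 0.02. Heat shock genes fell in 9 of 17 cases (median -0.28, camera adjusted p = 0.00073), with Hspa8 at -0.87 ± 0.04, and fibrosis genes fell in 8 of 19 cases (median -0.12, camera adjusted p = 0.0080). Lox was at -1.42 ± 0.07.

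Fat synthesis genes rose at the medium dose in 11 of 20 cases and fell in 5 (median 0.15, camera adjusted p = 0.046; adjusted p = 0.33 with an estimated correlation). Thrsp was at 0.98 ± 0.01 and Acaca at 0.81 ± 0.04. Mitochondrially encoded transcripts fell in 12 of 13 cases (median -0.36, camera adjusted p = 6.1e-05; adjusted p = 0.33 with an estimated correlation), and their share of the reads was 6.52% ± 0.37. The clock list rose in 10 of 17 cases (camera adjusted p = 0.040; adjusted p = 0.11 with an estimated correlation) and the cytochrome P450 list in 9 of 20 (camera adjusted p = 0.039; adjusted p = 0.20 with an estimated correlation). In glucose metabolism, where 6 genes rose and 8 fell of 18 (camera adjusted p = 0.55), G6pc (-0.84) and Pck1 (-0.49) fell. In total 5003 genes passed, 2599 higher and 2404 lower (3750 and 1438 as TPM), and the groups did not overlap for 49.2% of genes, against 10% by chance.

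High-dose plantain was compared with the obese control to ask what the largest dose changed. Acsm5, a mitochondrial acyl-CoA synthetase gene (ENSRNOG00000031211, chromosome 1, 189233141 to 189272172), rose from 18.6 ± 0.14 to 74.8 ± 0.76 FPKM (mean ± SD, n = 3), a log2 change of 1.95 ± 0.03 with an adjusted p of 1.68e-16. Nrg4 rose by 2.21 ± 0.11, the methyltransferase gene Inmt by 1.64 ± 0.10 and Cyp7a1 by 1.18 ± 0.03. Map2k3 rose by 1.82 ± 0.41, with reads that could be split with a second record of that name. LOC103690108 stood at 8.19 ± 1.13 FPKM where the obese control was listed at 0, in the on or off pattern by group given above. Akr1c2 fell (-2.62). Nfs1 (-3.27 ± 0.58) and Rps6 (-3.03 ± 0.83) were lower with the uncertainty given above. Srm (-2.48 ± 0.82) and LOC679739 (-2.25 ± 0.71) passed. The call on Srm ended without obese control replicate 1 (-2.17) or 3 (-1.68), in a fit of the 2 groups alone (adjusted p = 0.057) and with voom (adjusted p = 0.25). That on LOC679739 ended without obese control replicate 3 (-1.94) and with voom (adjusted p = 0.066).

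Endothelial markers rose at the high dose in 10 of 11 cases (median 0.75, camera adjusted p = 5.2e-08). Stab2 was at 1.10 ± 0.04, Lyve1 at 0.98 ± 0.04 and Kdr at 0.97 ± 0.04. The unfolded protein and amino acid stress list fell in 15 of 21 cases and rose in 2, or 16 and 4 adjusted over the list alone (median -0.27, camera adjusted p = 3.9e-05). Hyou1 was at -1.54 ± 0.04, Manf at -1.33 ± 0.04 and Hspa5 at -1.06 ± 0.02. Amino acid breakdown genes rose in 13 of 20 cases and fell in 4 (median 0.22, camera adjusted p = 0.0012). Sds was at 0.90 ± 0.02 and Cps1 at 0.54 ± 0.02. Kupffer cell markers fell in 9 of 13 cases, or 10 adjusted over the list alone, and rose in 1 (median -0.24, camera adjusted p = 0.0024). Cd5l was at -0.85 ± 0.04 and Marco at -0.81 ± 0.09. Mitochondrially encoded transcripts, also an RNA quality list, fell in 13 of 13 cases (median -1.05, camera adjusted p = 2.3e-09, and 0.18 with an estimated correlation). ND3 was at -1.43 ± 0.10, ND5 at -1.16 ± 0.05 and ND4L at -1.13 ± 0.08. The share of reads on mitochondrial transcripts was 4.64% ± 0.06 (mean ± SD, n = 3).

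Cholesterol genes rose at the high dose in 15 of 25 cases and fell in 6 (median 0.19, camera adjusted p = 0.040; adjusted p = 0.083 with an estimated correlation). Stard4 was at 0.79 ± 0.04. Heat shock genes fell in 7 of 17 cases (camera adjusted p = 0.040; adjusted p = 0.18 with an estimated correlation and 0.069 under quantile normalization), and growth hormone genes fell in 11 of 18 (camera adjusted p = 0.040; adjusted p = 0.18 with an estimated correlation and 0.069 under quantile normalization). Bcl6 was at -1.64 ± 0.05. Hepatocyte markers fell in 9 of 14 cases (camera adjusted p = 0.044; adjusted p = 0.32 with an estimated correlation), and quantile normalization turned the direction of that list. Of the lists that did not pass, fatty acid oxidation had 11 that rose and 8 that fell of 26 (camera adjusted p = 0.54). Cpt1a was at 0.75 ± 0.02 and the lipid droplet coat gene Plin2 at -1.19 ± 0.04. The NRF2 list had 8 and 5 of 18 (camera adjusted p = 0.23), with Gclm at 1.03 ± 0.02. Fat synthesis had 7 that rose and 10 that fell of 20 (camera adjusted p = 0.54), and bile acid genes had 7 and 7 of 18 (camera adjusted p = 0.49). The sterol exporter gene Abcg5 was at 0.92 ± 0.06. In total 6199 genes passed, 3181 higher and 3018 lower (5177 and 1475 as TPM), and the groups did not overlap for 57.8% of genes, against 10% by chance.

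**Figure D3:**
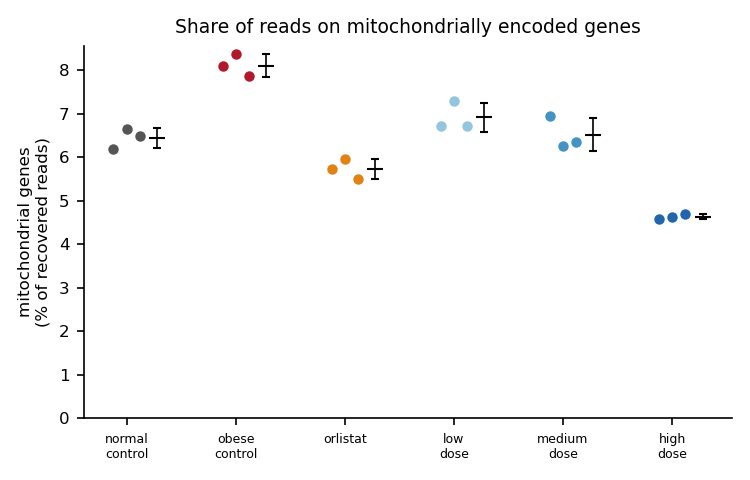
Percent of the recovered reads on mitochondrially encoded genes (vertical axis, from 0) in each of the 18 libraries, by group (horizontal axis). Points are libraries and the black mark with bars is the mean ± SD of 3 libraries; the mean was 8.11 in the obese control and 4.64 at the high dose.

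A trend over the obese control and the 3 doses, per step of dose rank, asked which genes followed the dose. Acsm5 (0.48 ± 0.01 per step), Gclm (0.34 ± 0.01), Adh1 (0.25 ± 0.01) and Thrsp (0.22 ± 0.01) rose. Akr1c2 (-0.91 ± 0.02), Srd5a1 (-0.37 ± 0.01), the stress-responsive factor gene Atf5 (-0.35 ± 0.01), Hspa5 (-0.34 ± 0.01) and RGD1307603 (-0.29 ± 0.01) fell. LOC103690108 also passed upward, but it was on or off by group. It stood at 0, 0.039, 11.2 and 8.19 FPKM in the obese control and at the low, medium and high dose. The trend did not mean a step at each dose: Acsm5 stood at 18.6, 39.5, 18.6 and 74.8 FPKM in the obese control and at the low, medium and high dose. Of the 6272 genes called, 3167 upward and 3105 downward (5232 and 1463 as TPM), group means were ordered by dose in 41.3%, against 25.3% of all tested genes. The trend itself favours genes with ordered means, and the tested genes include those called, so this excess is no evidence of a dose effect. Over the 3 doses alone 3210 of the 6272 genes passed in the same direction and 124 in the opposite one. Endothelial markers rose in 10 of 11 cases (0.24 per step, camera adjusted p = 1.5e-07), Kupffer cell markers fell in 12 of 13 (-0.13, camera adjusted p = 9.7e-06) and the unfolded protein list fell in 17 of 21 (-0.14, camera adjusted p = 2.6e-06). Mitochondrially encoded transcripts fell in 13 of 13 cases (-0.31, camera adjusted p = 5.4e-09; adjusted p = 0.16 with an estimated correlation). The calls on cholesterol genes (upward, 0.037), amino acid genes (upward, 0.031), heat shock (downward, 0.031), growth hormone genes (downward, 0.031) and hepatocytes (downward, 0.034) were lost as well, with adjusted p = 0.088, 0.078, 0.16, 0.16 and 0.32 with an estimated correlation; heat shock and growth hormone genes were at 0.070 and 0.067, and hepatocytes turned direction, under quantile normalization.

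The F-test of the low, medium and high dose gave 4588 genes that differed among the doses. After Acsm5, the genes with the smallest p were Scd, at 109 ± 2.33, 272 ± 3.16 and 170 ± 3.98 FPKM at the low, medium and high dose (adjusted p = 4.36e-15), the methyl transfer enzyme gene Bhmt, at 1070 ± 4.21, 914 ± 6.82 and 711 ± 3.40 FPKM, and Tsku, at 54.4 ± 1.47, 35.3 ± 1.24 and 88.4 ± 0.32 FPKM (mean ± SD, n = 3). Kng1, which encodes kininogen, stood at 940 ± 13.5, 475 ± 16.2 and 511 ± 5.76 FPKM, and Igfbp1, which binds insulin-like growth factors, at 56.2 ± 0.87, 17.7 ± 1.11 and 23.0 ± 0.30 FPKM. Srd5a1, RGD1307603, Thrsp and LOC103690108 were the others.

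High-dose plantain was also set against orlistat, the comparator of the study. Cish (2.00 ± 0.05, adjusted p = 6.28e-13, n = 3 per group), Socs2 (1.45 ± 0.07), Wfdc2 (1.60 ± 0.06) and the mitochondrial carrier gene Slc25a30 (1.36 ± 0.07) were higher at the high dose, and the prolactin receptor gene Prlr (-1.96 ± 0.06) and Bcl6 (-1.92 ± 0.05) were lower. Sccpdh (2.44 ± 0.77) was higher with wide spread, a call that ended without any 1 of the 6 libraries (2.38 to 2.53), with no filter on low values (adjusted p = 0.088), with robust moderation (0.073), with the replicate block (0.065) and with voom (0.18). Nfs1, LOC108352650 (-1.86 ± 0.45) and LOC100910882 (-1.84 ± 0.39) were lower, with spread between replicates or near copies that make them uncertain. Kupffer cell markers were lower in 12 of 13 cases (median -0.29, camera adjusted p = 8.0e-12), amino acid genes in 14 of 20 (median -0.18, camera adjusted p = 5.6e-11) with Tat at -0.71 ± 0.02, cholesterol genes in 13 of 25 (median -0.14, camera adjusted p = 2.5e-06) with Insig1 at -1.02 ± 0.04, and fibrosis genes in 5 of 19 (camera adjusted p = 0.013). NRF2 genes were higher in 10 of 18 cases (median 0.20, camera adjusted p = 2.4e-08) with Akr7a3 at 0.96 ± 0.05 and Ephx1 at 0.67 ± 0.02, fatty acid oxidation genes in 16 of 26 (median 0.12, camera adjusted p = 2.9e-05) with Cyp4a2 at 0.86 ± 0.03, and endothelial markers in 4 of 11 (median 0.11, camera adjusted p = 0.0013). Calls on mitochondrial transcripts (lower, 1.2e-11), oxidative phosphorylation (higher, 5.9e-05), heat shock (lower, 0.011), lipoproteins (higher, 0.017) and hepatocytes (higher, 0.024) were lost, with adjusted p = 0.079, 0.081, 0.081, 0.066 and 0.31 with an estimated correlation. Adjusted over the list alone, 14 cholesterol and 6 fibrosis genes were lower, 18 fatty acid oxidation, 13 oxidative phosphorylation and 5 endothelial genes were higher. In total 1806 genes passed, 1009 higher and 797 lower, and the groups did not overlap for 30.6% of genes, against 10% by chance.

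The treatments were set beside the obesity change, since each shares the obese control. Of the 367 genes that passed with a change over log2 1 in obese against normal controls, orlistat changed 290 in the opposite direction and 19 in the same one, the low dose 257 and 23, the medium dose 278 and 16, and the high dose 296 and 14. The median share of the obesity change opposed was 51.2%, 34.4%, 42.6% and 53.2%. The fatty acid and triglyceride synthesis list as a whole was not moved back. Against the normal control its median was -1.36 in the obese control. It was -1.4, -1.26, -0.96 and -1.26 with orlistat and at the low, medium and high dose. Against the obese control the treatments had medians of -0.11, -0.05, 0.15 and -0.14. Acly and Pnpla3, members of that list, were chosen after their values were seen. Acly stood at 15.7 ± 0.47 to 20.7 ± 1.03 FPKM in the treated groups and 17.0 ± 0.44 in the obese control, against 108 ± 0.68 in the normal control. Pnpla3 stood at 0.19 ± 0.05 to 0.69 ± 0.07 in the treated groups, against 11.7 ± 0.90 in the normal control. Across the 11945 genes, which are not independent replicates, the covariance of the log2 changes with the obesity change was -0.0917 for orlistat, -0.0599, -0.0778 and -0.0981 for the low, medium and high dose, against -0.00947, -0.00971, -0.00958 and -0.00963 in simulated unchanged groups with the same controls. The correlations were -0.59, -0.51, -0.57 and -0.62, against simulated values of -0.48, -0.49, -0.49 and -0.49. Of the genes that rose with obesity, 1875 fell with orlistat and 1883 at the high dose, against 816 and 806 for independent lists; of those that fell, 2111 and 2152 rose, against 888 and 902. Orlistat and the high dose had a covariance of 0.112 with each other, against 0.00945 simulated, and shared 2515 higher and 2343 lower genes, against 834 and 772 for independent lists. The 3 shared control libraries cannot be split, so part of the excess may come from the shared controls.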

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

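The tests of shared RNA, of the time of collection and of library noise were chosen after the results were seen; those of the obese control rats and of other splits were chosen before. Against the obese control, 1 of the 26 tested lists and 3 of the 10 genes named among doses passed in opposite directions at the low and the high dose, and the difference of the 2 doses passed as well. The 10 genes were those with the smallest p among the doses. A difference between 2 doses was therefore likely to pass and adds no support for them. Acsm5 and Scd also differed between the doses. The Kupffer cell and macrophage list had a median of 0.29 at the low dose and -0.24 at the high dose, and the median of its members' own differences between the doses was -0.59 (camera adjusted p = 4.2e-12; adjusted p = 0.00054 with an estimated correlation). The size of -0.24 rests in part on the deposited scale, since TPM moved the median of all genes by 0.15 at the high dose. Camera compares the list with other genes, which such a shift moves as well. The lists were not tested under TPM. Other lists also differed at the high against the low dose, given here with the median and camera's adjusted p with an estimated correlation. Lower were acute phase proteins (-0.16, 0.008), the unfolded protein and amino acid stress list (-0.25, 0.0079) and immediate early genes (-0.44, 0.008). Endothelial markers (0.28, 0.0026) and fibrosis and stellate cell genes (0.18, 0.018) were higher. Mitochondrially encoded transcripts fell in 13 of 13 cases (-0.78, camera adjusted p = 3.6e-12; 0.075 with an estimated correlation). Bhmt was at 0.51 ± 0.01 and -0.08 ± 0.01, a difference of -0.59 (limma adjusted p = 7.34e-14). The value of -0.08 is smaller than the 0.15 by which TPM moved the median of all genes at the high dose. Its direction therefore rests on the deposited scale. Tsku was at -0.32 ± 0.03 and 0.37 ± 0.03, a difference of 0.69 (adjusted p = 1.06e-10), and Igfbp1 at 0.75 ± 0.04 and -0.51 ± 0.04, a difference of -1.25 (adjusted p = 7.9e-12), with n = 3 libraries per group.

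The first pattern was that all 4 treatments moved against the obesity change, which each shares with the obese control libraries. The covariance nearest to 0 was -0.0599, at the low dose, against -0.00971 in simulated unchanged groups. Independent noise with the spread seen between libraries was therefore excluded as the whole cause. If the libraries of a group share RNA, that spread holds no difference between animals, so noise from animals was not excluded. By correlation the low dose was at -0.51, against -0.49 simulated. If the obese control rats themselves stood apart, the treatments would oppose the obesity change alike; the median share opposed ran from 34.4% to 53.2%, a span of 18.8 points, which does not decide. This and an effect of the treatments cannot be told apart, since all 4 treatments were compared with the same 3 libraries.

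The second pattern was the small spread within groups. If the 3 libraries of a group shared their RNA, genes that vary between single animals would spread no more than others: the immediate early, growth hormone and clock genes had a within-group SD of 0.88 times that of genes of like expression (50 genes; 1.08, 0.91 and 0.72 by list), and 2.5 times between groups. On the other side, 146 of 11945 tested genes reached 5 FPKM and differed at least 4-fold between libraries of a group. Among them were Nfs1 (6.23 ± 8.78 FPKM in the normal control), Tspan4 (6.03 ± 8.15 with orlistat) and Srm (9.53 ± 9.32 in the obese control). Such genes numbered 46 to 56 in each group, so some recurred between groups. For Nfs1 reads could be split between 2 records, so these genes need not mean that the RNA differed. In a search for a second gene that made up for the change, 12 of the 146 lost at least 75% of their sum of squares, against 6 to 17 in 20 shuffles of the libraries within groups, so reads moved between 2 copies were not seen. Reads spread over more than 2 copies were not searched for. LOC103690108 was on or off alike in the 3 libraries of each of the 6 groups, but this is 1 gene. Pairs of libraries of a group were also compared over genes with at least 20 reads in the pair. The median chi-square was 1.48 to 2.35 times that of read sampling alone, so most genes spread little beyond sampling. The small p-values above rest on this spread. How far separate animals would spread was not measured. Shared RNA and 3 separate animals that were alike cannot be told apart, since the lists spread little and the 146 genes spread widely for a cause not found.

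The third pattern was the clock. Time of collection that differed between groups would move the 2 arms of the clock apart, and they had medians of opposite sign in 5 of 5 comparisons with a control: 1.7 and -1.25 in obese against normal control, and -1.61 and 0.88 at the high dose. All 5 share the obese control, so a shift in that group alone would give the same signs. Of the 10 pairs of groups without it, 8 had medians of opposite sign. The low dose against orlistat (-0.12 and -0.22) and the high against the medium dose (0.03 and 0) did not. Groups collected at the same time would have medians near 0, so the pair at 0.03 and 0 does not count against time of collection. Time of collection and an effect of obesity or treatment on the clock cannot be told apart, since the labels give no time of collection and each group may have had its own. The same limit holds for any other gene or list above that follows the time of day, and which of them do was not tested.

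The 6 libraries of each comparison of 2 groups make 10 splits, too few for a share under 0.05. The real split, 1 of 10, gave 6578, 6188, 3947, 5003 and 6199 genes in the obesity, orlistat, low-, medium- and high-dose comparisons, and the highest other split gave 0, 2, 0, 1 and 0. For the high dose against orlistat the real split gave 1806 and the highest other 1. For the dose trend 1 of 100 splits, the real one, gave 6272 genes and the highest other 4031; among doses the values were 4588 and 2187. Chance was excluded for both only if the 3 libraries of a group came from separate animals, which is not known. These splits exchange single libraries, so they do not test a cause shared by all libraries of a group. The order of the doses was not tested by them either.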

How the results depend on the processing

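The alternatives were set before the data were examined, except voom on the recovered reads and the trend without the obese control, which were chosen after seeing the data. The counts of genes past the threshold stayed within 1.5 times of the reported ones under a pseudocount of 0.1, no filter, TPM, quantile normalization, fits of the compared groups, robust moderation, the replicate block and voom. The genes behind the counts changed more. Under TPM, 4746 of the 6188 genes called with orlistat were called again, as were 3485 of 3947 at the low dose, 4719 of 6199 at the high dose and 4701 of 6272 for the trend. Leaving out 1 library gave 5994 to 6107 genes in obese against normal control, 5566 to 5698 with orlistat, 3402 to 3485, 4410 to 4666 and 5597 to 5701 at the low, medium and high dose, 5771 to 6285 for the trend, 4045 to 4528 among doses and 1407 to 1454 for high dose against orlistat. Without the obese control the trend gave 3903 genes, with fewer samples and without the step from control to low dose, and the cause was not tested. The replicate numbers did not pair the libraries: 45 pairs of the same number had r of -0.092 to 0.066, and 2 of 18 libraries correlated best with their own number.

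With an estimated correlation, camera called 10 of 17 lists in obese against normal control, 4 of 8 with orlistat, 7 of 11 and 4 of 9 at the medium and high dose, 7 of 12 for high dose against orlistat and 3 of 9 for the trend. The fry rotation test called 25 lists with orlistat, 25, 23 and 23 at the low, medium and high dose, and 24 for the trend. With the replicate block 5 lists were called at the high dose, where cholesterol, heat shock, growth hormone and hepatocyte lists were at 0.05, and the medium-dose fat synthesis list was at 0.055. The cause was not tested.

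Under quantile normalization the hepatocyte list reversed in obese against normal control (camera's adjusted value 0.2), with orlistat (0.62), at the high dose (0.05) and in the trend (0.052). Single genes reversed as well: ATP6 (-0.033) and Ambp (-0.041) in obese against normal control; Hpx (0.042), Fga (0.108), Ttr (0.033) and Vtn (0.034) with orlistat; ATP6 (0.033) and Ambp (0.029) at the low dose; Vtn (0.083) at the medium dose. At the high dose Hpx (0.182), Fga (0.186), Ambp (0.042) and Vtn (0.055) reversed, and in the trend Apoa2 (0.03), Hpx (0.033), Fga (0.04), Ttr (0.005), Vtn (0.015) and Ambp (0.007). With TPM, Fga (0.057) and Vtn (0.006) reversed at the high dose. The cause was not tested. The gene results followed here were of genes picked for large changes or small p-values, so they do not stand for all genes called. Of 809 such results, 762 kept direction and call under quantile normalization, 772 under TPM, 805 with a pseudocount of 0.1, 798 with no filter, 787 in fits of the compared groups, 808 with robust moderation, 807 with the replicate block and 800 with voom.

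The covariances with the obesity change were -0.1618, -0.1156, -0.1481 and -0.1767 with a pseudocount of 0.1, for orlistat and the low, medium and high dose, and -0.05486, -0.03708, -0.04718 and -0.05876 with no filter, which adds genes near 0 FPKM. The cause of the first was not tested. Depth was not varied. In simulated counts 82 of 99 genes changed by log2 1 were recovered, with a median estimate of 0.85, and 37 of 40 among those of at least 10 FPKM, with 0.95. Whether depth or the pseudocount limited the genes of low FPKM was not tested.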

Other observations

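All values in this part were looked at after the results were seen. In the 12 treated libraries 294 genes were higher than in each of the 6 control libraries, normal and obese, and 280 were lower, of 11945. There are 15 ways to set 4 whole groups against 2, too few for a share under 0.05: 2 of them, the real one included, gave at least the real 574 genes, and the highest other, with the obese control and the low dose set apart, gave 879. The ways ranked 3 and 15 by this count gave 446 and 37. If whole groups exchange, each direction would hold at most 796 genes on average over the 15 ways. That bound is reached only if every tested gene is apart in 1 of the ways, so 294 and 280 under it decide nothing. Ces2e stood at 3.25 ± 0.14 to 11.3 ± 0.57 FPKM in the treated groups, against 0.17 ± 0.06 and 0.40 ± 0.07 in the normal and obese control (mean ± SD, n = 3). Kdr was at 9.97 ± 0.22 to 13.3 ± 0.53 FPKM, against 5.20 ± 0.06 and 6.29 ± 0.32, and Ptprb at 4.33 ± 0.19 to 6.16 ± 0.20, against 2.33 ± 0.15 and 2.07 ± 0.11. Angptl4, which encodes an inhibitor of lipoprotein lipase, was lower, at 34.1 ± 0.26 to 48.5 ± 2.32 FPKM, against 96.0 ± 1.44 and 60.7 ± 2.59.

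Set against the normal control, 25 of 25 cholesterol genes were lower with orlistat and at the low, medium and high dose (medians -0.65, -0.79, -0.69 and -0.78). Endothelial markers were higher in 10, 10, 10 and 11 of 11 cases (medians 0.89, 0.72, 0.74 and 0.96), and Kupffer cell markers in 13, 13, 10 and 10 of 13 (medians 0.73, 1.01, 0.36 and 0.42). Fibrosis and stellate cell genes were higher with orlistat and at the medium and high dose (medians 0.34, 0.22 and 0.29), and immediate early genes at the low dose (0.37, 11 of 15 cases). Mitochondrially encoded transcripts were lower at the high dose in 13 of 13 cases (median -0.65, camera adjusted p = 1e-07; adjusted p = 0.13 with an estimated correlation). Genes of glucose production and insulin response were lower in 12, 13, 12 and 11 of 18 cases. The unfolded protein list was lower with orlistat and at the medium and high dose (14, 14 and 13 of 21 cases), and did not pass at the low dose (camera adjusted p = 0.98).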
